A study of Mus musculus with 2 samples.

How the data were processed

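Small RNA was sequenced from exosomes, the small vesicles that cells release, of C57BL/6 mouse macrophages. The groups are M0-Exos and M1-Exos, with 1 library each, where M0 and M1 are the field's names for unpolarised and classically activated macrophages; how the cells were activated is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol. The protocols name both a TruSeq RNA kit and a small RNA library kit. The libraries are described here as small RNA libraries, following the series type. Bowtie is named, without a version, in the submitters' processing notes. The genome build, the miRNA database and its version, the mismatches allowed and the treatment of reads with several matches are not given in the sources used here.

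The authors deposited a table of 319 miRNA entries with a CPM value, the reads of an entry scaled to a fixed library total, for each library. Of that total, 113792 CPM (11.4%) of M0-Exos and 114420 CPM (11.4%) of M1-Exos were not accounted for by the entries of this table and were not analysed here. Within each library, 100% of the CPM values were whole multiples of the value of 1 read, within 0.1 read. This gave totals of 4394 reads for M0-Exos, where 1 read equals 228 CPM, and 12760 reads for M1-Exos, where 1 read equals 78.4 CPM. The unit planned for the main description, CPM, was kept, and the recovered reads were used for errors and for an added test. The authors also deposited a table of 319 KEGG pathways with, per the file headers, the number of target genes in each pathway, the number of genes in the pathway, an enrichment p-value and its adjusted p-value. According to the series design these are predicted targets of miRNAs that differed between the libraries. The target predictor, the miRNAs used and the background are not given in the sources used here.

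A single library per group leaves no spread between samples, so no difference between the libraries has a replicate check. Intervals are 95% exact intervals: Clopper-Pearson for shares, Poisson for levels and conditional binomial for ratios. A level of 0 reads allows up to 3 reads (a one-sided limit), which is 683 CPM (0.0683%) in M0-Exos and 235 CPM (0.0235%) in M1-Exos. The reads carry no molecular identifiers, so these intervals and floors cover counting error only. The planned description used log2 of (CPM + 1), with a pseudocount of 1 CPM, entries of 10 CPM or more in at least 1 library and a 2-fold threshold. This scale understates changes of low entries, though only slightly here for entries with reads in both libraries, since 1 read equals at least 78.4 CPM. At this depth it also turns any entry with 0 reads in 1 library into a large ratio.

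After the depth was known, each entry was also compared by a two-sided Fisher's exact test of its reads against the library total, with Benjamini-Hochberg adjustment over the 319 entries. Such a test compares these libraries, not the conditions, since libraries of the same condition also differ. A drop in abundant entries raises the share of all others, so the test was repeated with the reads of entries named with a hairpin arm (-5p or -3p) as the total. As a chance reference, all reads were pooled and split at random at the depths of the 2 libraries, 1000 times. An earlier form of this reference drew both libraries from the pooled composition; it was replaced after it was run because such draws lose rare entries, with a median of 290 entries holding reads against the 319 listed; it had given 68 to 96 entries at least 2-fold higher and 34 to 57 lower in 95% of draws.

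The groups, thresholds, lists and most alternative settings were fixed before the data were examined; Fisher's exact test, the limit of 20 reads, arm-named totals, thinning and the sums that leave out or add members of a list were added afterwards. The miRNA lists were miRNAs induced by inflammatory activation, linked to alternative activation, or enriched in myeloid cells; the let-7, miR-17 with its paralog clusters, miR-23 with miR-27 and miR-24, miR-29, miR-30, miR-181 and miR-15 with miR-16 families; the Dlk1-Dio3 and Sfmbt2 clusters; and markers of red cells, hepatocytes, epithelium, mesenchyme, lymphocytes, endothelium, neurons and muscle. Each list with at least 3 listed members had its median log2 ratio placed among the medians of 10000 random lists of the same size, matched on mean level, as a description of these libraries. Summed reads of the 19 lists with reads were compared by Fisher's exact test, which was added after the depth was known. The KEGG lists covered innate and inflammatory signalling, phagocytosis and antigen handling, growth and kinase signalling, cancer, and pathways chosen as unrelated. Entries were named by a rule of size: the 12 highest and the 12 lowest ratios, the 10 most abundant entries of each library and the members of the lists; entries called by the added test were named as well, after their values were seen.

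Hairpin positions came from the GENCODE release M21 annotation of GRCm38, where 284 of the 319 entries had a hairpin found by name. Hairpin sequences were compared with other noncoding RNAs of that annotation by BLAST+ 2.17.0 (at least 20 bases at 95% identity or more). 3' UTR lengths came from the same annotation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

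The added test was tested on 20 simulated pairs of libraries with the depths of M0-Exos and M1-Exos, 319 entries and 200 of them changed. Among entries expected to hold 20 or more reads, it called 53.3% of 2-fold changes, 87.8% of 4-fold changes and 0.857% of unchanged entries. Over all entries it called 20.9% of 2-fold changes and 31.3% of 4-fold changes, and 98.1% of the ratio intervals covered the simulated value. The simulated reads carried counting error only, and the library totals were held fixed. These rates therefore leave out the spread between libraries of a condition and the shift of shares when abundant entries change. Other pseudocounts, filters, scalings, summing of families, and other adjustments of the KEGG values were tried as alternatives.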

Results

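Exosomal small RNA was profiled in mouse macrophages to ask which miRNAs distinguish M1-Exos, vesicles of M1 macrophages that the study used to polarise other macrophages towards the M1 type, from M0-Exos. The data held 1 library of each kind, with recovered totals of 4394 reads for M0-Exos and 12760 reads for M1-Exos. These are the totals that the CPM values were scaled by, and need not be the numbers of reads sequenced. Of the 319 miRNA entries listed, 219 had reads in M0-Exos and 298 in M1-Exos, 198 had reads in both, 100 in M1-Exos alone and 21 in M0-Exos alone. Depth differed between the libraries: M1-Exos thinned at random to 4394 reads kept a median of 227 entries. Entries with at least 100 reads numbered 4 in M0-Exos and 30 in M1-Exos.

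The most abundant entries were largely the same in both libraries, with 8 of the top 10 shared. They joined miR-21a-5p, a widely expressed miRNA induced in activated macrophages, with the red blood cell miRNAs miR-451a and miR-486a-5p/miR-486b-5p, the miR-17 cluster member miR-92a-3p, miR-221-3p, and the less characterised entries miR-5119 and miR-5106. In M0-Exos miR-5119 led with 91033 CPM (400 reads), ahead of miR-5106 with 67137 CPM (295 reads), miR-451a with 47792 CPM (95% interval 41547 to 54712) and miR-21a-5p with 41875 CPM. In M1-Exos miR-451a led with 58307 CPM (54192 to 62652), ahead of miR-21a-5p with 56191 CPM, miR-5106 with 47727 CPM and miR-5119 with 31348 CPM (400 reads). The 10 most abundant entries held 36.5% (35.1 to 37.97, Clopper-Pearson) of M0-Exos reads and 33.1% (32.2 to 33.9) of M1-Exos reads. These shares counted both miR-486a-5p (96 and 298 reads) and miR-486b-5p (96 and 299 reads). Reads counted under both names would make the shares too high. miR-5124a with 18889 CPM and miR-6240 with 16841 CPM belonged to the top 10 of M0-Exos alone, and miR-144-3p with 24687 CPM and miR-25-3p with 19436 CPM to that of M1-Exos alone. In GRCm38, Mir451a lies at chromosome 11, 78073170 to 78073241, beside Mir144 at 78073005 to 78073070, both on the plus strand. Mir5119 lies at chromosome 11, 98262606 to 98262662, inside Cdk12, and Mir21a at chromosome 11, 86584067 to 86584158, inside Vmp1, each on the strand of its host gene.

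M1-Exos were compared with M0-Exos entry by entry to find the miRNAs that differed. miR-101a-3p showed the clearest gain, from 3869 CPM (17 reads) in M0-Exos to 16379 CPM (209 reads) in M1-Exos, 4.23-fold higher (95% interval 2.58 to 7.41). miR-20a-5p and miR-93-5p, members of the proliferation-linked miR-17 cluster and a paralog of it, were 3.96-fold (1.73 to 11.2) and 2.45-fold (1.45 to 4.44) higher, miR-182-5p was 3.10-fold higher (1.49 to 7.45), and the red cell miRNA miR-144-3p was 1.72-fold higher (1.31 to 2.29). miR-21a-5p was 1.34-fold higher (1.14 to 1.59). In the other direction miR-5119 was 2.90-fold higher in M0-Exos (2.52 to 3.34), miR-690 6.10-fold (2.75 to 14.5), miR-3960 23.2-fold (3.12 to 1031, on 8 reads against 1), miR-5124a 1.64-fold (1.24 to 2.16), miR-5106 1.41-fold (1.22 to 1.62) and miR-199a-3p, whose sequence and reads miR-199b-3p shares, 1.82-fold (1.25 to 2.64). miR-5119 had 400 reads in each library, so its ratio is that of the library totals and marks a smaller share, not fewer reads.

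These entries and miR-92a-1-5p, with 6 reads in M0-Exos and 0 in M1-Exos (95% lower limit of the M0-Exos to M1-Exos ratio 3.42), made up the 14 of 319 that passed a two-sided Fisher's exact test on recovered reads after Benjamini-Hochberg adjustment, 6 higher and 8 lower in M1-Exos, against 38 at an unadjusted p under 0.05. Adjusted p was 5.00e-10 for miR-101a-3p, 0.00232 for miR-144-3p, 0.00743 for miR-20a-5p, 0.00770 for miR-21a-5p, 0.00894 for miR-93-5p and 0.0195 for miR-182-5p in this exact test. Among the lower entries it was 2.14e-49 for miR-5119, 1.07e-04 for miR-690, 1.11e-04 for miR-5106, 0.00682 for miR-3960, 0.00899 for miR-92a-1-5p, 0.0127 for miR-5124a and 0.0326 for miR-199a-3p, again from the exact test. Mir101a lies at chromosome 4, 101346945 to 101347027, Mir20a at chromosome 14, 115044157 to 115044263, inside Mir17hg, Mir93 at chromosome 5, 138165523 to 138165610, inside Mcm7, and Mir690 at chromosome 16, 28599935 to 28600043, inside Fgf12. With the reads of the 282 arm-named entries as the total, miR-101a-3p (3.70-fold, adjusted p = 1.96e-07) and miR-20a-5p (3.46-fold, adjusted p = 0.0406) still passed the exact test as higher. miR-144-3p (1.51-fold, adjusted p = 0.0770), miR-93-5p (2.15-fold, 0.0811), miR-182-5p (2.71-fold, 0.103) and miR-21a-5p (1.17-fold, 0.442) no longer passed that exact test, though each ratio stayed above 1. miR-199a-3p, miR-199b-3p and miR-92a-1-5p stayed lower under these totals, and miR-143-3p, a miRNA of smooth muscle and fibroblasts, joined them at 0.561 of its M0-Exos share (adjusted p = 0.0132, exact test).

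On the planned scale, 117 entries were at least 2-fold higher and 53 at least 2-fold lower in M1-Exos. Of the 117 higher entries 100 had 0 reads in M0-Exos, and 48 of those rested on 1 read against 0. Random splits of the pooled reads gave 89 to 116 higher and 43 to 66 lower entries in 95% of 1000 splits, so the lower count lay within counting error and the higher count 1 entry above it. Among the 103 entries with 20 or more reads, 13 were at least 2-fold higher and 4 lower, against 0 to 6 and 0 to 4 in the random splits, and 86 were neither. Across these 103 entries, which are not replicates, Pearson's r of log2 CPM was 0.733, below the 0.916 to 0.965 of random splits. A single entry among them, miR-181b-5p, had 0 reads in M0-Exos against 22 in M1-Exos, a log2 ratio of 10.8 with the pseudocount. How far it alone lowered r was not computed, so the gap need not reflect the other entries. Spearman's rho was 0.863, for which no range of random splits was computed. Over all 319 entries r was 0.522, inside the range of 0.510 to 0.643 from splits, and rho was 0.774.

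The 12 highest ratios all belonged to entries without reads in M0-Exos. miR-181b-5p had 1724 CPM (22 reads, 95% lower limit of the ratio 1.89) and miR-151-3p 1489 CPM (19 reads, lower limit 1.61) in M1-Exos, with adjusted p = 0.0505 and 0.0974 in Fisher's exact test. For miR-379-5p (784 CPM) and miR-5121 (705 CPM) the lower limits of 0.772 and 0.680 left no detectable difference, and miR-136-5p (627 CPM), miR-224-5p and miR-6538 (470 CPM each), miR-28a-3p, miR-328-3p and miR-345-3p (5 reads each) and miR-15b-3p and miR-29c-3p (313 CPM each, the first by table order of 10 tied entries) lay below the M0-Exos floor of 683 CPM. The 12 lowest ratios all belonged to entries without reads in M1-Exos. After miR-92a-1-5p came miR-709 with 910 CPM in M0-Exos, then miR-140-5p, miR-30c-2-3p and miR-3535 with 683 CPM each, miR-200b-5p, miR-23b-5p and miR-6238 with 455 CPM each, and miR-1249-5p, miR-129-5p, miR-1946a and miR-214-3p with 228 CPM, or 1 read, each, the first by table order of 13 tied entries.

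**Figure D1:**
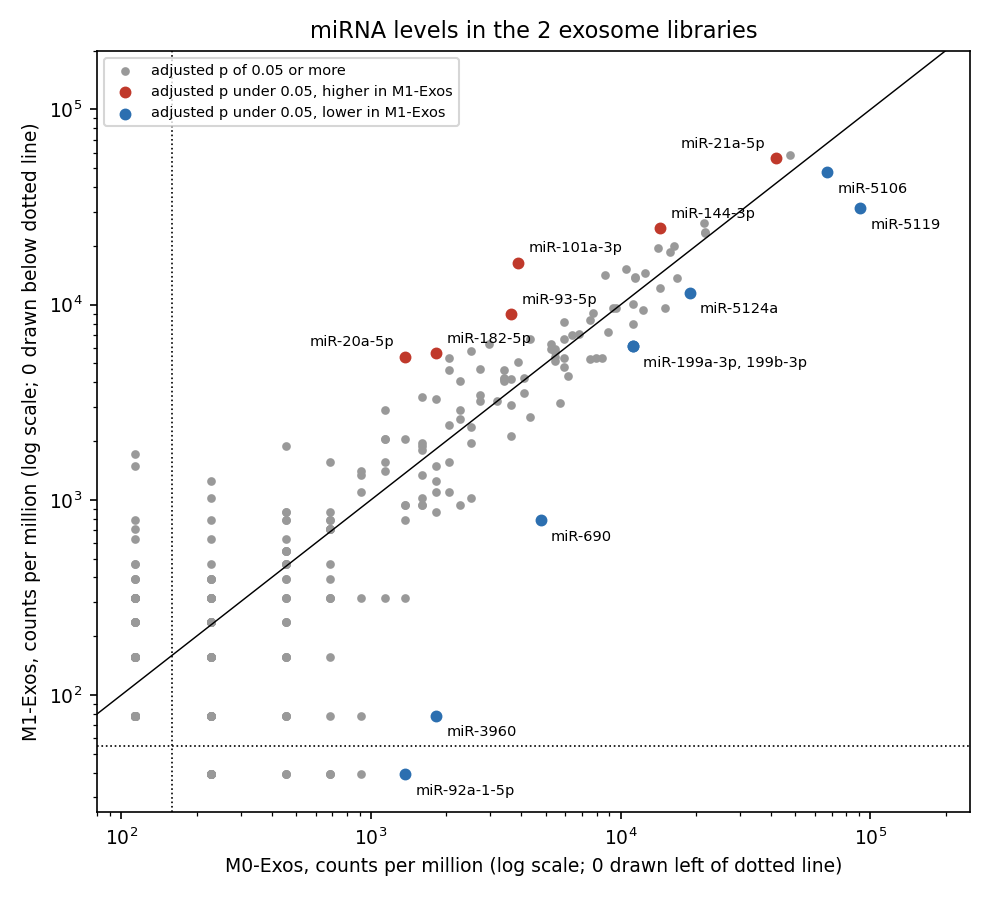
Level of each of the 319 miRNA entries in M0-Exos (x axis) and M1-Exos (y axis) in CPM on log axes, with 1 library per group; entries with 0 reads are drawn beyond the dotted lines and the diagonal marks equal levels. The 6 entries in red and 8 in blue passed Fisher's exact test on reads as higher and lower in M1-Exos, with miR-101a-3p far above the diagonal and miR-5119 below it.

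The lists of macrophage miRNAs addressed the activation state that the vesicles carried. Those induced by inflammatory activation held 7.99% (7.203 to 8.83) of reads in M0-Exos and 10.2% (9.71 to 10.8) in M1-Exos, a 1.28-fold rise (1.14 to 1.45; adjusted p = 6.42e-05, Fisher's exact test over 19 lists). Of the 16 of 20 members listed, 12 had reads in both libraries, and 10 of these were higher in M1-Exos. miR-155-5p, the central inducible miRNA of M1 activation, had 1 read in M0-Exos and 4 in M1-Exos, 228 CPM (5.76 to 1268) and 313 CPM (85.4 to 803), a ratio of 1.38 (0.136 to 67.8) in which no difference was detectable at this depth. Mir155 lies at chromosome 16, 84714140 to 84714204, inside its host gene Mir155hg. miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, had 8648 CPM and 14185 CPM, a ratio of 1.64 (1.15 to 2.39; adjusted p = 0.0722, exact test). miR-221-3p had a ratio of 1.22 (0.932 to 1.60), and miR-147-3p, miR-132-3p and miR-212-3p had at most 3 reads in either library.

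The rise of the inflammatory list rested on miR-21a-5p and miR-146a-5p. Over all entries 1 member, miR-21a-5p, was called, and 2 were called when adjusted over the list alone. Without miR-21a-5p the list's ratio was 1.22 (1.02 to 1.45), and without miR-146a-5p as well it was 1.09 (0.891 to 1.34). Among arm-named reads the whole list's ratio was 1.12 (0.995 to 1.26; adjusted p = 0.111, exact test). Its median log2 ratio was 0.38, at the 72.4th percentile of matched random lists, 0.05 with entries at 0 set to 3 reads and 0.10 after centring on the median of all entries. Red cell markers moved in the same direction by a similar factor, 1.25-fold.

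miRNAs linked to alternative activation did not differ detectably, with 1.37% of reads in M0-Exos and 1.61% in M1-Exos, a ratio of 1.18 (0.878 to 1.60; adjusted p = 0.420, exact test). Of 8 members 5 were listed, none was called, also when adjusted over the list alone, and 4 with reads in both libraries were all nominally higher, such as miR-223-3p with 6372 and 6975 CPM. The list's median log2 ratio of 0.19 (54.8th percentile) became -0.09 when ratios were centred on the median of all entries, which lay at 0.28. That median includes 100 entries with reads in M1-Exos alone and 21 with reads in M0-Exos alone. It was 0.19 over entries with 20 or more reads. A trimmed mean over entries with reads in both libraries gave a shift of -0.05, of the opposite sign. Values after centring, here and for other lists, therefore depend on the reference chosen. Myeloid-enriched miRNAs held 1.68% and 2.15%, a ratio of 1.28 (0.983 to 1.67; adjusted p = 0.160, exact test), with a median log2 ratio of 0.46 at the 89.5th percentile, 0.18 after centring and 0.25 with entries at 0 set to 3 reads. None of the 7 myeloid members was called, also when adjusted over the list alone. miR-142a-5p, a miRNA of blood cells, had 5917 and 8150 CPM, and miR-146b-5p had 2 and 24 reads, a ratio of 4.13 (1.03 to 36.1; adjusted p = 0.371, exact test). The alternative activation list shares miR-223-3p (28 and 89 reads) with the myeloid list. It also shares let-7c-5p (16 and 53 reads) with the let-7 family, so these lists are not separate evidence.

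Among the miRNA families, the miR-17 cluster with its paralogs rose most clearly, from 5.35% (4.70 to 6.06) of reads in M0-Exos to 8.28% (7.80 to 8.77) in M1-Exos. The rise was 1.55-fold (1.34 to 1.79; adjusted p = 1.36e-09, Fisher's exact test) and stayed at 1.35-fold (1.17 to 1.57; adjusted p = 5.75e-05, exact test) among arm-named reads. All 12 members with reads in both libraries were higher in M1-Exos, with 2 called over all entries and 3 when adjusted over the list alone. Besides miR-20a-5p and miR-93-5p, miR-19b-3p had a ratio of 2.32 (1.22 to 4.84), miR-17-5p 1.54 (0.929 to 2.68), miR-25-3p 1.38 (1.04 to 1.85) and miR-92a-3p 1.21 (0.958 to 1.53). Without miR-20a-5p and miR-93-5p the summed ratio was 1.41 (1.21 to 1.65). Of 3 other arms of these hairpins outside the list, miR-92a-1-5p was called lower with 6 and 0 reads, miR-20a-3p had 1 and 1 reads and miR-25-5p 3 and 9, and with them the summed ratio was 1.498 (1.30 to 1.73). Red cell markers (1.25-fold) and lymphoid markers (1.71-fold) rose in the same direction. The median log2 ratio of the list was 0.88, at the 99.6th percentile of matched random lists, 0.70 with entries at 0 set to 3 reads and 0.60 after centring.

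The let-7 family, abundant in differentiated cells, had 6.21% and 5.46% of reads, a ratio of 0.878 (0.762 to 1.01; adjusted p = 0.160, exact test). Among arm-named reads that ratio was 0.768 (0.666 to 0.886) and passed the exact test (adjusted p = 9.67e-04). Its median log2 ratio was 0.04 (36.1th percentile) and -0.25 after centring, so its median and its summed reads differed in sign. The miR-23, miR-27 and miR-24 list behaved alike, with a ratio of 0.850 (0.705 to 1.03; adjusted p = 0.160, exact test) and 0.743 (0.616 to 0.900; adjusted p = 0.00726, exact test) among arm-named reads, and a median log2 ratio of 0.02 (10.3th percentile) that became -0.26 after centring. Neither family had a called member, also when adjusted over the list alone. miR-29 (0.649, 0.396 to 1.09), miR-30 (0.974, 0.781 to 1.22), miR-181 (1.52, 0.969 to 2.48) and miR-15 with miR-16 (1.32, 0.940 to 1.89) gave ratios of summed reads whose intervals included 1. Among arm-named reads the interval of miR-29 did not (0.567, 0.346 to 0.951), but its adjusted p was 0.102 in the exact test. Their median log2 ratios were 6.31, -0.08, 3.78 and 0.74, and -1.12, -0.08, -0.14 and -0.32 with entries at 0 set to 3 reads, so those of miR-29, miR-181 and miR-15 with miR-16 changed sign. Of these families only miR-181 had a member, miR-181b-5p, called when adjusted over the list alone.

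Markers of other cell types were compared in the same way. Red cell miRNAs made up 10.8% (9.89 to 11.7) of reads in M0-Exos and 13.5% (12.9 to 14.1) in M1-Exos, a 1.25-fold rise (1.13 to 1.39; adjusted p = 2.31e-05, Fisher's exact test) in which all 5 members were nominally higher. These values counted the reads of miR-486a-5p and miR-486b-5p under each name. Counted once, the shares were 8.60% (7.79 to 9.47) and 11.2% (10.6 to 11.7), a ratio of 1.298 (1.16 to 1.46). Of the 5 members, 1 was called over all entries and 3 when adjusted over the list alone, miR-144-5p having 2048 and 5329 CPM. The rise did not pass among the arm-named reads, which leave out miR-451a (1.12, 0.975 to 1.29; adjusted p = 0.199, exact test), and the median log2 ratio of 0.29 (85.3th percentile) became 0.01 after centring. Both the arm-named test and the median counted miR-486 under each of its names. Among arm-named reads no ratio was computed with miR-486 counted once, so whether the rise is absent there is not settled. Mesenchymal markers fell from 5.62% (4.96 to 6.34) to 4.05% (3.72 to 4.41), a ratio of 0.721 (0.618 to 0.842; adjusted p = 1.03e-04, exact test), and 0.630 (0.540 to 0.736; adjusted p = 3.35e-08, exact test) among arm-named reads. The fall rested on miR-199a-3p, miR-199b-3p and miR-143-3p, the members called over the list alone (2 of them over all entries). Counting the shared miR-199-3p reads once gave 0.764 (0.644 to 0.908), and leaving out these 3 gave 0.987 (0.766 to 1.28), with miR-10b-5p at 1593 and 3370 CPM. Both list tests above counted the shared miR-199-3p reads under each of the 2 names. With the full totals, the unadjusted p of the exact test was 2.16e-05 counted so and 0.00164 counted once. Among arm-named reads no p was computed with these reads counted once. The mesenchymal median log2 ratio was -0.34, at the 10.5th percentile, -0.62 after centring and -0.13 with entries at 0 set to 3 reads.

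Lymphoid markers rose 1.71-fold (1.13 to 2.67; adjusted p = 0.0282, exact test), but not among arm-named reads (1.495, 0.990 to 2.33; adjusted p = 0.123, exact test) or without miR-181b-5p (1.44, 0.946 to 2.26), and miR-150-5p, a miRNA of mature lymphocytes, had 5 and 37 reads. Their median log2 ratio was 1.35 (97.6th percentile), and 1 of 3 listed members was called when adjusted over the list alone. Besides miR-150-5p the listed members were miR-181a-5p (23 and 80 reads) and miR-181b-5p (0 and 22 reads). Both also belong to the miR-181 list, with its ratio of 1.52 (0.969 to 2.48), so these lists are not separate evidence. Epithelial markers had a ratio of 1.21 (0.835 to 1.78) and a median log2 ratio of 0.05 (23.5th percentile), -0.23 after centring and -0.73 with entries at 0 set to 3 reads, with miR-182-5p called, both over all entries and when adjusted over the list alone, and miR-200b-3p at 2503 and 1019 CPM. Without miR-182-5p the epithelial ratio was 0.700 (0.445 to 1.12). Hepatocyte markers had a ratio of 0.689 (0.430 to 1.13; median log2 ratio -0.50, 4.37th percentile, -0.78 after centring), and of 0.602 (0.376 to 0.985; adjusted p = 0.111, exact test) among arm-named reads, with the liver miRNA miR-122-5p at 2503 and 2351 CPM. Endothelial markers stood at 1.18 (0.841 to 1.67) and neural markers at 1.10 (0.386 to 3.85; median log2 ratio 0.27, 35.8th percentile, -0.01 after centring). Muscle markers had 1 and 8 reads, too few to show a difference (adjusted p = 0.550, exact test). None of the hepatocyte, endothelial, neural or muscle members was called, also when adjusted over the list alone.

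**Figure D2:**
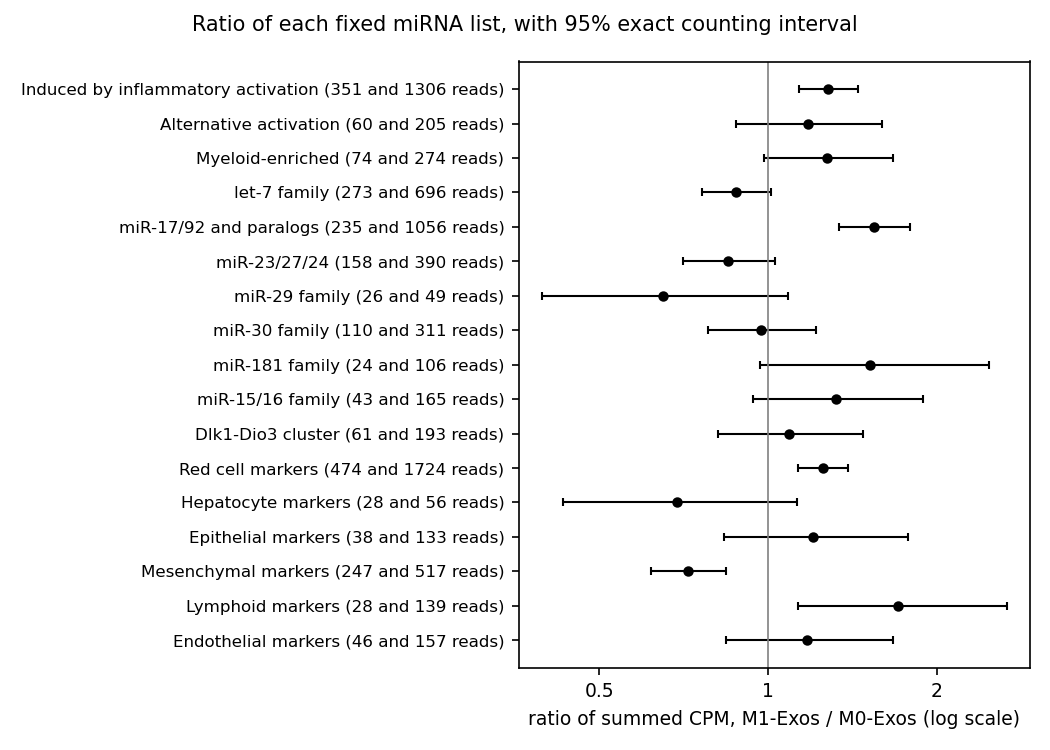
Ratio of the summed CPM of M1-Exos to M0-Exos for each fixed miRNA list (points, log axis) with its 95% exact counting interval (bars), and the reads of each list in M0-Exos and M1-Exos in parentheses. The miR-17 cluster with its paralogs lies at 1.55, the red cell markers at 1.25 and the mesenchymal markers at 0.721; the line marks a ratio of 1, and neural and muscle markers, with few reads, are not drawn.

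The study then asked which pathways the predicted targets of the differing miRNAs fall into. In the authors' deposited table, 9 of 319 pathways passed an adjusted p of 0.05, led by Wnt signalling, a pathway of development and cell fate, with 131 of 148 genes listed as targets (88.5%, adjusted p = 1.74e-04). MicroRNAs in cancer (124 of 142, adjusted p = 9.10e-04), Hippo signalling (129 of 151, 0.00457), breast cancer (125 of 147, 0.00712), parathyroid hormone action (92 of 107, 0.0175), stem cell pluripotency (114 of 135, 0.0175), gastric cancer (123 of 148, 0.0346), sphingolipid signalling (99 of 118, 0.0486) and FoxO signalling (109 of 131, 0.0486) followed in the authors' deposited table. The next pathway of the authors' deposited table, renal cell carcinoma, had 59 of 68 genes and an adjusted p of 0.0710. Wnt, Hippo, breast cancer, pluripotency and gastric cancer shared the same gene families in the authors' deposited table, each listing 19 Wnt ligands and 8 Frizzled receptors among its targets.

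None of the 10 innate and inflammatory pathways passed in the authors' deposited table, where 53 of all 319 had an unadjusted p under 0.05, among them 1 of these 10. TNF signalling came closest in the authors' deposited table, with 88 of 109 genes (80.7%, adjusted p = 0.188), while Toll-like receptor signalling had 72 of 98 (adjusted p = 0.790), NF-kappa B signalling 68 of 92 (adjusted p = 0.771) and cytokine-cytokine receptor interaction 189 of 285 (66.3%, adjusted p = 1). Of 12 growth and kinase pathways 3 passed (78.9% of their summed genes were targets), and of 6 cancer pathways 2 passed (79.8%), again in the authors' deposited table. None of the 7 phagocytosis and antigen pathways found passed (73.5%), T cell receptor signalling having 84 of 100 genes and an adjusted p of 0.0710 in the authors' deposited table. Of the 6 pathways chosen as unrelated none passed (69.3%), with 57 of 129 genes (44.2%) for the ribosome and 140 of 174 (80.5%, adjusted p = 0.0866) for axon guidance in the authors' deposited table. Olfactory transduction supplied 1110 of their 1774 summed genes, so the 69.3% rests largely on it. The authors' unadjusted p was under 0.05 for 2 of these 6, 9 of the 12 growth and kinase, 5 of the 6 cancer and 3 of the 7 phagocytosis and antigen pathways. The authors' deposited table named 5593 distinct target genes, and 72.5% of all summed pathway genes were targets, against 72.2% in the innate and inflammatory list. The authors' deposited table does not say which miRNAs or which direction of change the targets came from.

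**Figure D3:**
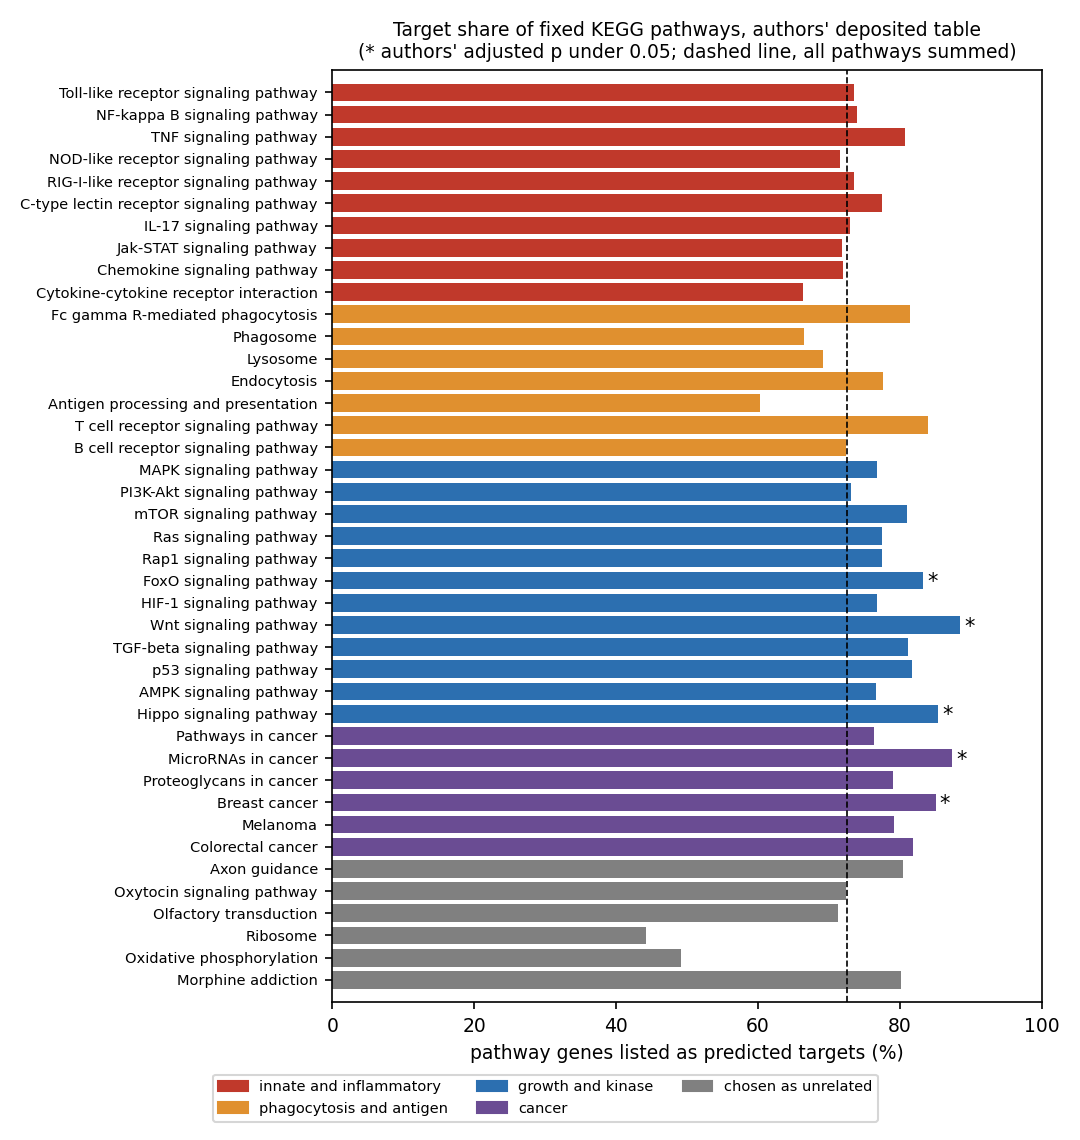
Percentage of the genes of each fixed KEGG pathway listed as predicted targets in the authors' deposited table (bars from 0, coloured by list), with the 72.5% of all pathways summed as a dashed line and a star for an authors' adjusted p under 0.05. Wnt signalling reaches 88.5%, TNF signalling 80.7% and the ribosome 44.2%.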

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

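Of the values below, Fisher's exact test, the limit of 20 reads, arm-named totals and thinning were tests chosen after the depth had been seen; the others were planned. The number of entries at least 2-fold higher in M1-Exos, 117 as reported, was 69 with a filter of 100 CPM, 65 with arms and copies of a numbered family summed, 72 with M1-Exos thinned to the M0-Exos depth, 13 with 20 or more reads and 6 by the exact test. The number lower, 53, was 29 with families summed, 4 with 20 or more reads and 8 by the exact test. The limit of 20 reads removes entries resting on few reads by construction. The filter of 100 CPM acts on 1 side only. It removes entries with 1 read in M1-Exos alone (78.4 CPM) but keeps those with 1 read in M0-Exos alone (228 CPM). The number lower stayed at 53 under it. A filter of 10 CPM removed no entry, so setting it against none tests nothing. The correlation between libraries, 0.522 as reported, was 0.383 with a pseudocount of 0.1 CPM, 0.700 with 10 CPM and 0.733 with 20 or more reads. The 10 most abundant entries, with both copies of miR-486 counted, held 41.2% of the listed reads in M0-Exos and 37.3% in M1-Exos. In the authors' deposited table, 4 pathways passed an adjusted p of 0.01 and 4 passed a Bonferroni adjustment. Of 98 alternative list medians 95 stayed within counting error and 3 moved, as did 172 and 4 of 176 for named entries. These tallies are weak evidence of stability. The entries named for the highest and lowest ratios had 0 reads in 1 library, so their intervals had no limit on 1 side. miR-1249-5p, with 1 read against 0, counted as unmoved at log2 ratios of -7.84, -11.15 (pseudocount of 0.1 CPM) and -4.57 (10 CPM). The miR-181 median counted as unmoved at 3.78 and, from summed CPM, at 0.60. No entry called by the exact test changed sign, but centring took miR-21a-5p from 0.42 to 0.14. In at least 1 setting the medians of the alternative activation, let-7, miR-23 with miR-27 and miR-24, miR-29, epithelial and neural lists changed sign, as did the ratios of miR-486a-5p, miR-486b-5p and miR-92a-3p, entries that were not called. Causes were not tested further. No paired analysis was possible because each group has 1 library, so none could be left out either.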

Other observations

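The tests of red cell miRNAs, the search for a tRNA motif and the totals of arm-named reads were chosen after their results or the entries had been seen; the tests of a single abundant entry, of noncoding RNA matches and of 3' UTR length were set before. miRNAs of the imprinted Dlk1-Dio3 cluster, active in stem and mesenchymal cells, were present at a low level, with 1.39% of M0-Exos and 1.51% of M1-Exos reads over 23 of 34 members, a ratio of 1.09 (0.813 to 1.48). Its leading member miR-127-3p had 5462 and 5172 CPM, and no member was called, also when adjusted over the list alone. The cluster's median log2 ratio was 0.78 (69.0th percentile) with the pseudocount and -1.12 with entries at 0 set to 3 reads, 10 of its members having no reads in M0-Exos. None of the 22 members fixed for the rodent Sfmbt2 cluster was listed, which allows up to 0.0683% of M0-Exos and 0.0235% of M1-Exos reads for it if its members would have been listed. Within the epithelial miR-183 cluster, miR-182-5p had 8 and 72 reads while its neighbour miR-183-5p had 7 and 17, a ratio of 0.836 (0.330 to 2.39), and miR-96-5p had 1 and 3.

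Red cell miRNAs were among the most abundant entries of both libraries. Counting miR-486a-5p and miR-486b-5p once, which had 96 reads each in M0-Exos and 298 and 299 in M1-Exos, left them 8.60% of M0-Exos reads and 11.2% of M1-Exos reads, so double counting does not account for their abundance. A candidate explanation is RNA or vesicles from serum or blood: miR-122-5p, a liver miRNA of plasma, had 11 reads (5.49 to 19.7) in M0-Exos and 30 (20.2 to 42.8) in M1-Exos, as that would need. Red cell precursors among the cultured cells would give the same shares, and these sources cannot be told apart here, because no library of medium or of the cells themselves was analysed. The difference between M0-Exos and M1-Exos itself stays open, with 1 preparation of each.

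Entries named without a hairpin arm, a class that holds many weakly supported miRNA annotations, took 28.0% (26.7 to 29.4) of M0-Exos reads and 19.3% (18.6 to 19.96) of M1-Exos reads, a ratio of 0.687 (0.641 to 0.736). Without miR-5119 the ratio was 0.852 (0.786 to 0.924), so that entry carries much of the difference but not the whole. Fragments of other noncoding RNAs are a candidate explanation that cannot be settled: the 6 entries whose hairpins match such RNAs had a ratio of 0.756 (0.596 to 0.963) against 0.677 (0.630 to 0.728) for the 28 without a match, but leaving out the well supported miR-451a, miR-484 and let-7j, a choice tried first and not part of the prediction, put the latter at 0.540 (0.497 to 0.588), below the matched entries, and leaving out miR-5119 as well returned it to 0.698 (0.627 to 0.779). The annotation used lacks nuclear tRNA genes and most ribosomal DNA, and a match to the A box of tRNA genes was found in 2 of 34 hairpins without an arm name, those of miR-5106 and miR-5112, and in 0 of 193 with one. A difference between M0 and M1 vesicles in such RNA was not tested.

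In the authors' deposited table the share of a pathway's genes listed as targets rose with the median 3' UTR length of its listed genes, with Spearman's rho of 0.559 (0.458 to 0.647, bootstrap) across 273 pathways, which share genes and are not independent. The listed genes of Wnt signalling had a median of 1702 bases, those of the ribosome 558 and those of oxidative phosphorylation 475, while olfactory transduction with 1913 goes against the trend at 791 of 1110 genes, again in the authors' deposited table. Longer 3' UTRs hold more predicted sites for any miRNA set, so UTR length may account for part of the ranking; a biological role of these pathways in M1-Exos was not tested.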
